A study of Bos taurus with 6 samples.

How the data were processed

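The series holds 6 polyA RNA-seq libraries, each from 1 bovine morula: 3 controls in 0.1% DMSO and 3 embryos in 20 µM FIDAS-5. Per the submitters' processing notes, TopHat2 2.0.14 and Cufflinks 2.2.1 were used with the genome build bosTau8. The authors deposited 1 Cufflinks gene table per library with FPKM values and their confidence bounds, also in FPKM, per the file headers. The settings and the gene annotation are not given in the sources used here. Gene identifiers made by Cufflinks show that each library was assembled on its own with an annotation as a guide, which can merge neighbouring genes in one library and not in another. No scaling between libraries is recorded. FPKM values of annotated genes summed to between 922067 and 975224 per library.

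The tables hold 43390 to 68286 rows. Unannotated rows numbered 29294 to 54215 per library and were not used for expression, since loci of about 99 bases reach up to 24949300 FPKM. Between 8.28% and 10.6% of annotated rows have an FPKM outside their own bounds, so the bounds were not used as an error. Rows of 1 symbol were summed. Of 13295 symbols present in all 6 libraries, 13185 were kept. The 110 left out were 38 that also share a merged locus in some library and 72 with a status other than OK. Over all libraries 639 genes share a merged locus, most of them without a row of their own in every library. Interferon tau genes fall in a merged locus. Exact zeros occurred in genes with otherwise ample expression: of 4874 genes that reach 10 FPKM, 130 were at 0 in some library. Such genes are described as listed at 0, with the value of each library and no fold change.

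Depth was recovered from the confidence bounds of unannotated loci of 100 to 300 bases, which step by whole fragments. With a tolerance of 0.05, 99.7% to 99.9% of the values came out whole at the depths given, and 48.8% to 51.6% with that depth divided by 2. Depth was 46500000 to 59900000 fragments per library. Counts per gene were not recovered, so no counting interval is given and errors are the spread between embryos. No 2 libraries shared a measurable percent of equal values above 0 (highest 0%), so none was counted as a duplicate.

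Genes at 1 FPKM or more in at least 3 of the 6 libraries were tested, 7319 in all. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, no block, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. Gene lists with at least 5 tested genes, 29 of 34, were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, for change in one direction and in either direction. Single values were compared with an exact two-sided permutation test, whose smallest p is 0.1 here. For each chromosome with at least 30 tested genes, the median difference of a library from the mean of the other 5 was set against 2000 random gene sets matched on mean expression, adjusted over 180 pairs. A shift was counted beyond 0.2, a bound chosen after the values were seen.

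The design, gene lists, alternatives and naming rule were written before the data were examined. The rule names MAT2A and POU5F1, NANOG, SOX2, CDX2, GATA3, TEAD4, GATA6, DNMT1, DNMT3A and DNMT3B. It then names up to 10 genes per direction that passed, not overlapping between groups and with a symbol, filled up to 10 with the smallest p, and the 3 members of each list with the smallest p, or up to 5 where few passed. The 8 members of the unfolded protein response list that passed over the list alone were named after their values were seen. So were KRT8, VIM, DPPA2, DCN, LUM and the genes used as examples of zeros. No row carries the symbols TEAD4 or GATA6. Some genes that the rule selects are not reported here. Positions are those of the files, 1-based.

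The gene test was tried on simulated libraries with 200 of 7319 genes changed, in 10 runs. The changed genes were drawn only from those with a higher mean, and changes were added on the log2(FPKM + 1) scale. Recovery among low genes was therefore not measured. With each gene's own SD the gene test recovered 18.7% of 2-fold, 68.5% of 4-fold and 87.5% of 8-fold changes. Of these, 0 had the wrong sign, with 6.7 false calls per run. In simulations that shuffled the SDs between genes it recovered 10.2%, 58.7% and 81.3%. Camera called a simulated rise of the unfolded protein response list by 0.5 on the log2 scale in 100% and 98% of 50 runs. It called the same list in 0% when left unchanged. Other lists, all unchanged, were called 0.04 times per run with own SDs and 0.08 times with shuffled SDs. These runs hold no correlation between genes, so they do not test the preset value.

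Alternatives were another scaling (TPM, median-of-ratios, quantile), a pseudocount of 0.1, other filters, no trend, array weights, the replicate number as a block, 1 row per symbol, no X or Y genes, no genes with a 0, and each library left out in turn. Added after the data were seen were fits without the 2 treated libraries with Y-linked transcripts, with merged loci given to each gene, and without chromosomes 14, 15, 27 and 28, and the fry test of change in either direction.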

Results

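Single bovine morulae produced by in vitro fertilization were sequenced after exposure to FIDAS-5, an inhibitor of MAT2A, the enzyme that makes S-adenosylmethionine from methionine and ATP. Treatment with 20 µM FIDAS-5 began at 72 h after insemination (day 3), when embryos had 8 to 16 cells, and ended at 144 h (day 6). Control embryos received 0.1% DMSO, the solvent of the inhibitor, and oxygen was held at 5%. The labels give no DMSO content for the treated embryos. Each group held 3 libraries, each made from 1 embryo with a polyA-based full-length kit for low input. The depth recovered from the steps of the deposited values was 56500000, 53400000 and 59900000 fragments in controls 1 to 3 and 54000000, 46500000 and 57700000 in MAT2A-inhibited morulae 1 to 3. Expression is given in FPKM, and fold changes are MAT2A-inhibited minus control on the log2(FPKM + 1) scale, which understates the change of low genes. The labels do not say that the embryos came from separate cultures, so p-values measure the spread between these embryos.

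The first question was whether the transcript of the inhibited enzyme differed. MAT2A (bosTau8 chromosome 11, 49298513 to 49305179) was at 74.8, 79.2 and 74.2 FPKM in controls and at 91.4, 53.2 and 70.5 FPKM in MAT2A-inhibited morulae, or 76.1 ± 2.74 against 71.7 ± 19.1 (SD, n = 3 each, exact permutation p = 0.7). The log2 fold change was -0.12 ± 0.24 (SE) with a limma adjusted p of 0.914. The smallest p that 3 against 3 can give in the permutation test is 0.1. Without MAT2A-inhibited replicate 2 the log2 fold change was 0.08, so its sign rests on that library. A catalytic inhibitor need not alter the transcript, and the value does not check the labels.

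The DNA methyltransferases, which use S-adenosylmethionine, varied between embryos of the same group. DNMT1, the maintenance enzyme, was at 4.25 ± 1.42 FPKM in controls and 5.45 ± 1.70 in MAT2A-inhibited morulae. The de novo enzyme DNMT3A was at 5.78, 4.28 and 27.7 FPKM against 47.6, 10.3 and 17.4, and DNMT3B was at 5.50, 0.07 and 22.3 FPKM against 8.04, 5.80 and 24.5. Among lineage genes, POU5F1 was at 361.5 ± 61.9 against 319.3 ± 61.2 FPKM, and SOX2 at 33.7 ± 7.12 against 48.8 ± 3.09 FPKM (SD, n = 3). NANOG was at 4.58, 20.3 and 2.54 FPKM in controls and 1.17, 1.71 and 1.88 in MAT2A-inhibited morulae. The groups did not overlap for NANOG and SOX2, yet the limma adjusted p was 0.746 for both. CDX2 was low in both groups, at 1.59 ± 1.25 against 1.49 ± 1.20 FPKM. GATA3 ranged from 6.50 to 83.4 FPKM within the controls and from 15.5 to 33.9 in MAT2A-inhibited morulae. TEAD4 and GATA6 were not analysed here.

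**Figure D1:**
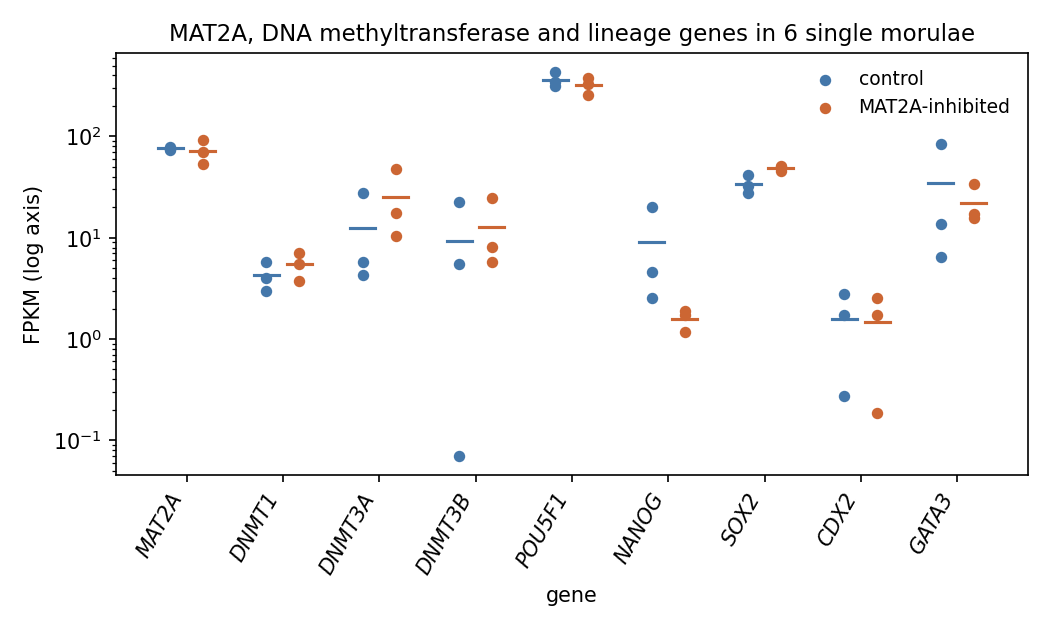
FPKM (log axis) of MAT2A, 3 DNA methyltransferases and 5 lineage genes, 1 point per embryo, with a bar at each group mean. MAT2A lies between 53.2 and 91.4 FPKM in all 6 morulae, while GATA3 in controls runs from 6.50 to 83.4 FPKM.

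Genes of the unfolded protein response, which raise folding capacity in the endoplasmic reticulum, were higher as a set in MAT2A-inhibited morulae by camera with its preset correlation. The call was lost with an estimated correlation (adjusted p = 0.713) and with fry, which tests whether members move one way (adjusted p = 0.129). Of 20 tested members, 19 had a log2 fold change above 0 and the median was 0.82. HSPA5, the main chaperone of that compartment (chromosome 11, 96115225 to 96119266), was at 72.5 ± 15.3 FPKM in controls and 223.1 ± 66.1 FPKM in MAT2A-inhibited morulae (SD, n = 3). XBP1, a transcription factor of the response, was at 19.7, 13.9 and 21.6 FPKM against 35.1, 70.9 and 63.7 FPKM. HSP90B1, PDIA4 and DNAJB11, which fold or oxidise secreted proteins, had log2 fold changes of 1.13, 1.40 and 0.95. SEC61B, of the translocation channel, HYOU1 and MANF had 1.20, 1.02 and 0.94.

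The preset correlation was 0.01 (camera p = 1.1e-10, adjusted p = 3.19e-09 over 29 lists). The correlation estimated for this list was higher, at 0.16, and with it the unadjusted camera p was 0.0246. The fry test of change in either direction, which sets a list against no other genes, gave an adjusted p = 0.012 and called 4 of the 29 lists, but 0 without control 1 and 0 without control 3. With the replicate block, or without the 2 libraries with Y-linked transcripts, none of these 4 lists was called by it. The 8 members named above passed limma when adjusted over the list alone, with adjusted p from 0.012 to 0.0288, and 0 passed over all genes tested. For 11 of the 20 members the 3 treated values all lay above the 3 controls. Y-linked transcripts were found in MAT2A-inhibited morulae 2 and 3, where the list mean was 0.85 and 0.92 above the control mean on the log2 scale. The treated embryo without them lay 0.54 above.

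**Figure D2:**
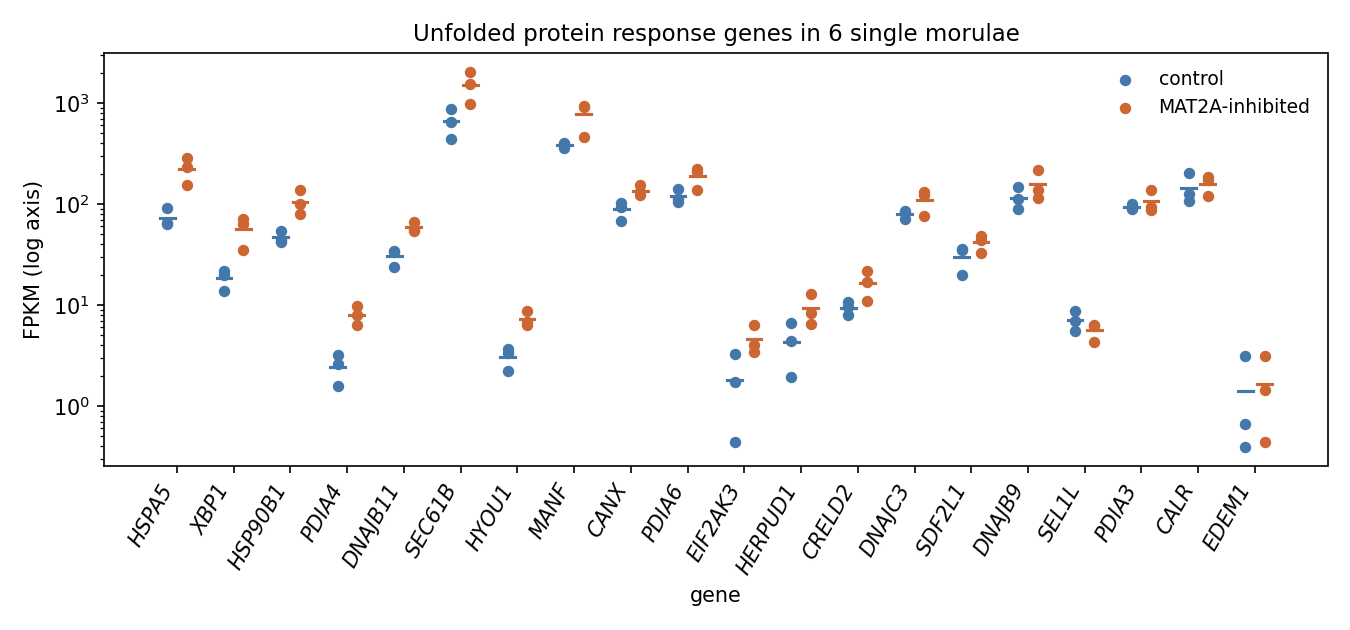
FPKM (log axis) of the 20 tested unfolded protein response genes, ordered by limma p, 1 point per embryo, with a bar at each group mean. HSPA5 is at 62.8 to 90.2 FPKM in controls and 152.5 to 283.4 FPKM in MAT2A-inhibited morulae.

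Gene by gene, few differences passed. ZBTB8OS (chromosome 2, 121817700 to 121830223) was listed at 0 in every control and at 46.2, 45.6 and 53.5 FPKM in MAT2A-inhibited morulae (limma adjusted p = 0.000323). CDKN3, a phosphatase of cyclin-dependent kinases (chromosome 10, 67155073 to 67172760), was listed at 0 in every control and at 10.5, 19.04 and 13.5 FPKM after treatment (adjusted p = 0.0102). DNAH7, an axonemal dynein heavy chain (chromosome 2, 84773343 to 85028058), was at 7.30, 14.8 and 21.6 FPKM in controls and listed at 0 in every MAT2A-inhibited morula (adjusted p = 0.0461).

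These 3 genes, 2 higher and 1 lower, were the whole of the 7319 tested genes that passed, and all 3 are listed at 0 throughout one group. A 0 in these files can be a failed estimate: TPM3, CBX5 and IDH3B, which most cells use, were each listed at 0 in 1 library and at 66.8 FPKM or more in the others. Leaving out MAT2A-inhibited replicate 1, 2 or 3, or every gene with a 0, left 0 calls. Leaving out control 3 gave 8, with 2 of the 3 genes among them. Part of this loss was fixed by the filter, which asks for 1 FPKM in 3 libraries. ZBTB8OS and CDKN3 were not tested without 1 treated library, nor DNAH7 without 1 control, nor any of the 3 without genes at 0. DNAH7 stayed in the test without a treated library and was not called. With no filter on low values, a mean of at least 5 FPKM, or the replicate number as a block, 1 gene was called, ZBTB8OS each time, and array weights called 5. An unadjusted p below 0.05 was found for 486 genes, 271 higher and 215 lower, where chance gives 366 for independent genes. Of the other splits of the 6 libraries, 2 gave more, at 519 and 572 genes. The groups did not overlap for 13.4% of tested genes, where chance gives 10% and another split also gave 13.4%.

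The next genes in order of p did not pass and are given as values. NUP160, a nuclear pore protein, was at 18.4 ± 3.24 FPKM in controls and 58.8 ± 1.36 FPKM in MAT2A-inhibited morulae (SD, n = 3). HEATR3 was at 14.3 ± 2.66 against 42.9 ± 6.26 FPKM, STYK1 at 6.84 ± 2.19 against 21.5 ± 3.29 FPKM, and B3GNT6 at 0.194 ± 0.172 against 4.99 ± 2.05 FPKM. SARS2 was listed at 0 in every control and reached 6.68 FPKM, and RETSAT was at 0, 0 and 0.101 FPKM against 3.43, 2.49 and 2.76. In the other direction, SREK1IP1 was at 95.4 ± 28.7 against 24.4 ± 3.57 FPKM and the transcription factor USF1 at 70.9 ± 21.2 against 11.02 ± 8.93 FPKM. POLRMT, the mitochondrial RNA polymerase, was at 17.0 ± 2.22 against 5.72 ± 0.556 FPKM. GTF2H2 was at 101.3 ± 18.2 against 49.1 ± 4.29 FPKM, the condensin subunit NCAPD2 at 28.4 ± 13.4 against 6.16 ± 1.76, and HPDL at 6.57 ± 3.44 against 0.844 ± 0.145. CRYBA1 was at 16.2, 5.73 and 8.39 FPKM against 0, 0 and 0.373, and ZNF268 at 10.8, 5.15 and 24.1 FPKM against 0 in each. SH3BGRL, on chromosome X, was at 33.8 ± 9.31 against 10.4 ± 2.28 FPKM. Their limma adjusted p ran from 0.125 for CRYBA1 to 0.661 for HPDL.

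Lists tied to methyl-group supply and use did not pass camera. Values given for their members are log2 fold changes unless FPKM is stated, and the median SE of a log2 fold change over all tested genes was 0.34. In the methionine and folate cycle, 8 of 22 tested genes had a log2 fold change above 0 (camera adjusted p = 0.758), with SHMT1 at 0.72 and MAT2B, the regulatory partner of MAT2A, at -0.29. Polyamine genes ODC1, AZIN1 and the X-linked SAT1 were at 1.002, -0.42 and -0.83 (list adjusted p = 0.758, 10 genes). In the DNA methylation machinery UHRF1, which brings DNMT1 to replicated DNA, was at 7.04, 5.53 and 5.29 FPKM in controls and 2.25, 2.78 and 0.797 FPKM after treatment (list adjusted p = 0.973). Among 25 histone and arginine methyltransferases SETDB1, EZH2 and EED had log2 fold changes of 1.34, 1.19 and -0.71 (adjusted p = 0.424). Histone demethylases JMJD6, KDM5A and KDM4A were at 0.41, -0.56 and -0.23 (adjusted p = 0.859). RNA methylation genes YTHDC1, IGF2BP1 and FTO were at 0.48, 0.83 and 0.76, with 17 of 21 members above 0 (adjusted p = 0.413). IGF2BP1 was at 140.1, 38.3 and 47.9 FPKM in MAT2A-inhibited morulae 1 to 3, against 30.1, 48.4 and 30.2 FPKM in controls. Phosphatidylcholine genes PCYT1A, PISD and CEPT1 were at -0.93, 0.56 and -0.28 (adjusted p = 0.853). Without MAT2A-inhibited morulae 2 and 3, which hold Y-linked transcripts, SAT1, JMJD6 and KDM4A were at 0.012, -0.089 and 0.315.

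Genes whose silencing depends on DNA methylation did not pass camera as sets over all 6 libraries. Of 7 tested germline genes, HORMAD1, a meiotic chromosome protein, was at 3.12, 2.46 and 2.53 FPKM in controls and 0.18, 0.091 and 0.891 FPKM in MAT2A-inhibited morulae, and passed limma adjusted over the list alone (adjusted p = 0.0198). MAGEB16, on chromosome X, and DDX4 had log2 fold changes of -1.49 and 1.49 (list adjusted p = 0.384). The fry test of change in either direction gave the germline list an adjusted p of 0.0021, a call lost with a pseudocount of 0.1. Imprinted genes BLCAP, GNAS and TSSC4 were at 0.83, 0.50 and 0.60, with 8 of 10 members above 0 (camera adjusted p = 0.384). Against the control mean, the list mean was 0.586, 0.134 and 0.587 in MAT2A-inhibited morulae and 0.278, -0.407 and 0.129 in controls. Camera called the imprinted list without MAT2A-inhibited morulae 2 and 3, a fit that leaves 1 treated embryo.

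Development and lineage lists did not pass camera either. Among maternal transcripts, ZP3, a zona pellucida protein, was at 3.19, 2.64 and 7.46 FPKM against 0.51, 0.724 and 1.35, and DPPA3, a maternal factor that guards methylation, was at 856.4, 660.9 and 881.3 FPKM against 527.2, 453.5 and 574.5. Both passed limma adjusted over the list alone (adjusted p = 0.033 each, 6 genes), but not over all genes tested (0.688 and 0.701). OOEP had a log2 fold change of 0.97. The list adjusted p was 0.469 with camera and 0.012 with the fry test of change in either direction. The pluripotency list, led by DPPA3, NANOG and SOX2, gave an adjusted p of 0.758. Trophectoderm genes KRT7, DAB2 and SLC2A3 were at 1.27, -0.42 and 0.32 (adjusted p = 0.758), and the keratin KRT8 ran from 4.49 to 400.5 FPKM within the controls. Primitive endoderm genes PDGFRA and RSPO3 were at -0.68 and 0.53, and LAMB1 was listed at 0, 0 and 17.5 FPKM against 9.84, 12.6 and 38.2 (list adjusted p = 0.973). Compaction genes CLDN3, F11R and OCLN were at 1.01, 0.51 and 0.71 (adjusted p = 0.413), and camera called this list without control 3. Of the genome activation list 4 genes were tested, too few for the set test: ZFAND2A 1.28, the X-linked EIF1AX -0.62, HSPA1A 0.13 and DPPA2 -0.02. EIF1AX was at 1257.3 and 1091.7 FPKM in the 2 libraries with Y-linked transcripts and at 2160.5 to 2331.4 FPKM in the other 4. Without those 2 libraries EIF1AX and SLC2A3 were at 0.028 and -0.039.

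Metabolic and stress lists other than the unfolded protein response did not pass camera. In glycolysis, PKM, which makes pyruvate, was at 10.3, 13.8 and 12.6 FPKM in controls and 50.8, 25.7 and 32.2 FPKM after treatment. PKM passed limma adjusted over the list alone (adjusted p = 0.0386), but not over all genes tested (0.573). PGK1, on chromosome X, and ALDOA were at -0.58 and 0.80 (list adjusted p = 0.859 with camera and 0.0366 with the fry test of change in either direction). The fry call was lost with the genes of X and Y left out and with a pseudocount of 0.1. Of 71 oxidative phosphorylation genes 53 were above 0, led by UQCR11 (0.65), COX6B1 (0.66) and ATP5G2 (0.86), with a list adjusted p of 0.384. Of 77 ribosomal protein genes 55 were above 0, with RPL37A at 0.35, RPL13A at 0.37 and the X-linked RPS4X at -0.51 (adjusted p = 0.384), and camera called them with no filter on low values. Their many processed copies can share reads. ATF4 targets WARS, EIF4EBP1 and PSAT1 were at 0.64, 0.69 and -1.08, with 15 of 24 below 0 (adjusted p = 0.758). Heat shock and immediate early genes IER3, HSPB1 and HSP90AA1 were at 1.02, 1.54 and 0.45, with 16 of 20 above 0 (adjusted p = 0.384). Oxidative stress genes SQSTM1, NFE2L2 and NQO1 were at 0.91, -0.55 and 1.03 (adjusted p = 0.413), and camera called this list without control 3. NFE2L2 and NQO1 also led the aryl hydrocarbon receptor list, followed by ARNT at -0.28 (adjusted p = 0.853).

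The other lists gave no call with camera or fry over all 6 libraries. Cholesterol genes NSDHL, on chromosome X, HSD17B7 and FDFT1 were at -0.75, -0.92 and -0.41 (camera adjusted p = 0.758). Fatty acid genes ACADM, ELOVL5 and DGAT2 were at -0.50, 0.40 and -0.54 (adjusted p = 0.973). In the list of p53 targets and DNA damage genes, H2AFX, FAS and CHEK2 were at 0.48, 1.04 and 0.53 (adjusted p = 0.853). Apoptosis genes CASP6, BAD and BID were at -0.50, 0.61 and 0.43, and cell cycle genes MCM5, MCM6 and TTK at 1.13, -0.47 and 0.47 (adjusted p = 0.859 for both lists). Interferon genes B2M and IRF1 were at -0.57 and 0.26 (adjusted p = 0.758). Lysosome and autophagy genes LAMP2, on chromosome X, SQSTM1 and ATG13 were at -0.77, 0.91 and 0.64 (adjusted p = 0.883), and fry in either direction called this list without control 2. Over the 28 lists that camera did not call, medians ran from -0.14 to 0.51. No member of the 34 lists passed limma over all genes tested. Adjustment over a list alone does not allow for the number of lists searched. An unadjusted p below 0.05 was found for 11 members of the unfolded protein response list and for at most 4 members of any other list.

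Markers of other cell types varied in level. The cumulus genes COL1A2 and STAR stayed at or below 4.29 FPKM in every library. DCN was at 11.002 FPKM in control 2 and at most 0.73 in the others. LUM was at 4.81 FPKM in control 2 and at most 0.739 in the others. SERPINE2 was at 53.9 to 121.8 FPKM in controls and 41.0 to 80.2 in MAT2A-inhibited morulae. VIM, the intermediate filament of mesenchymal cells, was at most 0.501 FPKM. The sperm genes TNP2, TNP1 and PRM1 reached 6.43, 5.56 and 2.17 FPKM. The blood gene HBA was at 132.4, 121.4 and 63.1 FPKM in controls and 109.8, 80.1 and 82.3 FPKM in MAT2A-inhibited morulae, a log2 fold change of -0.16, while HBB was at most 1.72 FPKM. ALAS2, on chromosome X, had a log2 fold change of -1.04.

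The number of genes at 1 FPKM or more was 7169, 7000 and 7176 in controls and 7361, 7015 and 7237 in MAT2A-inhibited morulae, or 7115 ± 99.7 against 7204 ± 175.3 (SD, n = 3, exact permutation p = 0.4). Spearman correlation across genes averaged 0.92 within groups and 0.915 between them. The first principal component held 31.1% of the variance and did not part the groups, with controls at -10.6, -51.1 and 23.6 and MAT2A-inhibited morulae at -0.2, 7.7 and 30.6. The second held 20.8% and parted them, with controls at 15.7, 0.9 and 36.3 and MAT2A-inhibited morulae at -7.1, -32.9 and -12.9. Chance parts 3 libraries from 3 on a given component in 10% of splits. Controls 2 and 3 correlated at 0.891, the other control pairs at 0.925 and 0.926, and the 3 pairs of MAT2A-inhibited morulae at 0.925 to 0.929.

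Chromosomes stood apart in single embryos. In control 1 the genes of chromosome 27 lay 0.58 below, and those of chromosome 15 lay 0.51 below, the level of random gene sets matched on expression, while chromosomes 14 and 28 lay 0.35 and 0.33 above on the log2 scale. Chromosome X lay 0.73 and 0.53 below in MAT2A-inhibited morulae 2 and 3, and 0.27 to 0.34 above in the other 4 libraries, which were compared with a mean that includes both low libraries and is lowered by them. XIST, the transcript that silences 1 X chromosome, was at 12.8, 61.3 and 7.49 FPKM in controls, 7.92 in MAT2A-inhibited morula 1, and 0.164 and 0.127 in the 2 libraries with a low X. Of 180 pairs of library and chromosome, 20 had an adjusted p below 0.05 against 2000 random sets, and 11 of these were also beyond 0.2, 6 of them on X. Tested X genes had a median log2 fold change of -0.47 against 0.06 on autosomes, and of the X genes with an unadjusted p below 0.05, 43 were lower and 0 higher in MAT2A-inhibited morulae.

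**Figure D3:**
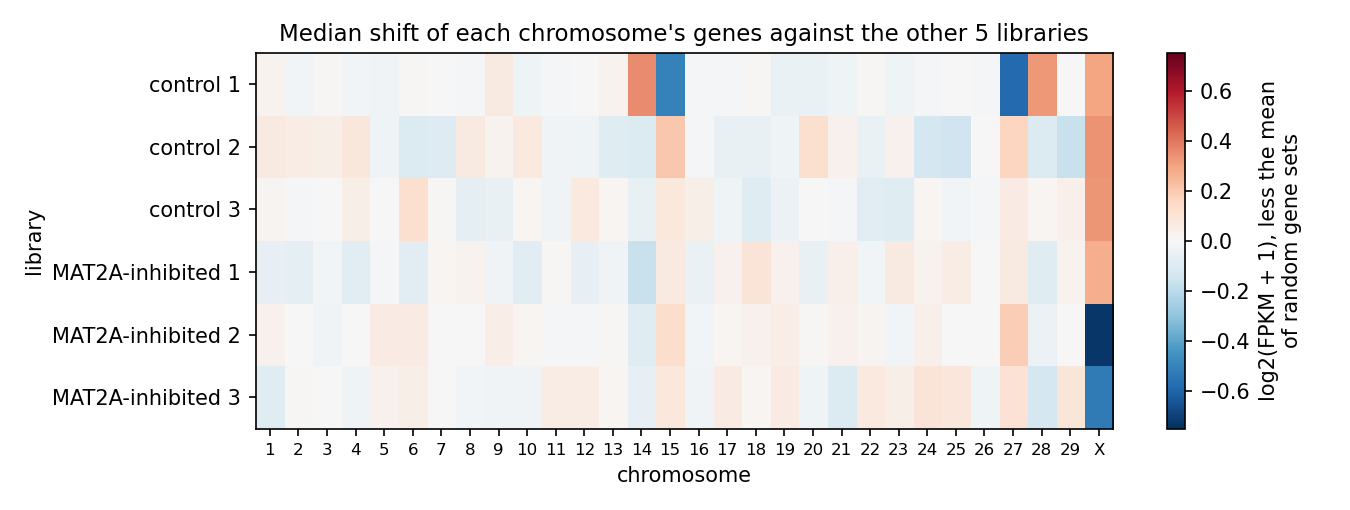
Median shift of each chromosome's genes in each library against the other 5 libraries, as log2(FPKM + 1) less the mean of random gene sets. Control 1 stands out on chromosomes 14, 15, 27 and 28, and MAT2A-inhibited morulae 2 and 3 on X, at -0.73 and -0.53.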

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

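The tests of embryo sex, of the ATF4 targets, of overlapping loci and of chromosome X were chosen only after the results were seen.

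Y-linked genes, which fail the expression filter and enter no test of the main fit, gave a signal in 2 MAT2A-inhibited morulae above every control. EIF1AY was at 38.2 and 106.9 FPKM in MAT2A-inhibited morulae 2 and 3 and listed at 0 in the other 4 libraries. DDX3Y was at 14.96 and 7.94 FPKM there and USP9Y at 4.10 and 1.496 FPKM, against at most 0.193 FPKM for either in the controls. OFD1Y reached 1.79 FPKM. Chromosome X lay lower in both of these libraries (highest -0.51) than in any library without Y-linked transcripts (lowest 0.26), as male and female embryos would give. The labels do not give the sex, and with all 3 controls lacking these transcripts, sex and treatment overlap in part.

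In the unfolded protein response list, other scalings argue against a scaling effect. The lowest list median was 0.769, while the median of all tested genes ran from -0.006 to 0.045 over these fits and the main one. The highest camera adjusted p was 2.71e-09. Camera sets a list against the other genes, so a scaling of whole libraries moves its p little. Camera p-values here use the preset correlation. The call was lost with an estimated correlation (adjusted p = 0.713) and with fry (adjusted p = 0.129). Of the 20 tested members 0 lie on X, so none of the 11 with an unadjusted limma p below 0.05 could lie there. Members on X thus cannot account for the rise, an outcome fixed by the list itself. The mean of the ATF4 targets was -0.08 against 0.77 for the list, so a rise shared by both lists is not seen. Against embryo sex, the treated embryo without Y-linked transcripts lay 0.539 above the control mean (highest control 0.052, itself part of that mean). In that embryo 13 of 20 members lay above every control, and the share over all tested genes was not taken. The list median without the Y-positive libraries was 0.57, a value that rests on that same embryo. Sex stays open, since 1 library excludes nothing and the 3 other splits in which camera called the list (adjusted p = 0.00858, 0.0151 and 0.000962) are those that keep MAT2A-inhibited morulae 2 and 3 together. Of 10 splits, 1, the real one, gave a camera p as small (1.1e-10, next 3.32e-05), but 10 splits cannot give a share under 0.05, so an effect of the inhibitor remains a hypothesis.

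For genes listed at 0 throughout one group and at 1 FPKM or more throughout the other, the real split held 6, among them CDKN3, DNAH7, SARS2, ZBTB8OS and ZNF268. Another split of the libraries held 9, so estimates that fail gene by gene may give as many. Overlapping unannotated loci of 1 FPKM or more lay in 50% of the libraries at 0 and in 55.6% of those above 0. They were thus no more frequent where a gene was at 0. An overlap does not show whether reads were taken, so the shares cannot settle it for single genes. DNAH7 and ZNF268 had such a locus in every library, at 0 or above, and SARS2 in none. Of the 10 splits, 2 called 3 genes or more, the highest of the other splits being 3. No biological explanation can be told from these values, since reads are not analysed here.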

How the results depend on the processing

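The fits without the 2 treated libraries with Y-linked transcripts, with merged loci, and without 4 chromosomes, and fry in either direction, were chosen after seeing the data. The 3 genes called became 1 without a filter, with a mean of at least 5 FPKM and with the replicate block, and 5 with array weights. They became 0 without genes at 0, a fit that leaves out all 3 by its rule. Without the 2 Y-positive libraries, 1 treated embryo is left and is assumed to vary like the controls. ZBTB8OS and CDKN3 then fail the filter, so no count of genes is given for that fit. Leaving out 1 library gave 0 to 8, but the filter dropped ZBTB8OS and CDKN3 without 1 treated library and DNAH7 without 1 control. Merged loci gave 2. Same-numbered libraries deviated together at r = 0.046, 0.103 and 0.191, and 5 of 6 correlated best with their own number, a hint only; the labels do not pair them. The block changed no camera call of a list. Lists called numbered 1, but 3 without a filter (ribosomal proteins and Y-linked genes added), 0 with an estimated correlation and 0 with fry. They numbered 4 with fry in either direction (germline, maternal and glycolysis lists added). With 1 library left out, camera called 1 to 3 (compaction and oxidative stress added without control 3). Without the Y-positive libraries camera also called imprinted genes, a call that rests on 1 treated embryo. The unfolded protein response median stayed at 0.825 with an estimated correlation (adjusted p = 0.713), fry (0.129) and fry in either direction (0.012). It was 0.57 without the Y-positive libraries, where 1 treated embryo is left. Fry in either direction called 1 list with the block (DNA methylation machinery), 1 without the Y-positive libraries (aryl hydrocarbon receptor), so that all 4 lists lost this call in both, and 0 to 4 with 1 library left out, where the unfolded protein response kept it only without MAT2A-inhibited replicate 1. Lists it added were lysosome and autophagy without control 2, ribosomal proteins without MAT2A-inhibited replicate 1 or 2, and histone methyltransferases without MAT2A-inhibited replicate 2. Of these 4, the germline and glycolysis lists lost it with a pseudocount of 0.1, glycolysis without X and Y genes, all but the unfolded protein response without a filter, and the germline and maternal lists were not called with a mean of at least 5 FPKM. The trend setting does not enter camera. In the remaining fits the unfolded protein response median was 0.64 to 0.96 with an adjusted p of at most 7.12e-07. MAT2A expression changed by 0.262 without the Y-positive libraries and -0.307 to 0.077 with 1 library left out. Genes detected differed by 11 to 184 with 1 library left out. Chromosome shifts numbered 12 with a mean of at least 5 FPKM and 10 with median-of-ratios scaling.

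Over 119 named genes, 2352 of 2395 values kept direction and side of the threshold, and 12 were weaker and 2 stronger. The other 29 changed sign, with limma adjusted p of 0.88 or more. Only 3 genes passed in the main fit, so most agreement is among values that never passed. Genes that a filter removed from a fit gave no value there and are not counted. Without the Y-positive libraries the sign turned for CDX2 (0.592), GATA3 (-0.225), SAT1 (0.012), JMJD6 (-0.089), KDM4A (0.315), SLC2A3 (-0.039), EIF1AX (0.028), MCM5 (-0.258), ARNT (0.22), STAR (-0.19) and HBA (0.125). GATA3 was -0.001 with median-of-ratios and -0.023 with quantile scaling, and HSPA1A -0.218 with array weights. With 1 library left out, CDX2 ran from -0.508 to 0.398, GATA3 from -0.691 to 1.054, DNMT3B from -0.083 to 2.139, KDM4A from -0.503 to 0.072, HSPA1A from -0.127 to 0.511, CEPT1 from -0.494 to 0.138, ARNT from -0.563 to 0.136, IRF1 from -0.078 to 0.505 and HBA from -0.493 to 0.035. The cause was not tested. Depth was 46500000 fragments or more in every library, and the counting error of single genes was not estimated.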

Other observations

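The tests on secretory genes used lists written after the unfolded protein response result was seen, the tests on parts of chromosomes were set after the shifts of whole chromosomes were seen, and the fry test of change in either direction was added after the data were seen.

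Other genes of the secretory pathway lay slightly higher in MAT2A-inhibited morulae. SURF4, a cargo receptor, was at 7.43, 9.71 and 11.995 FPKM in controls and 14.9, 22.1 and 22.3 FPKM after treatment, and SRPR, of the signal recognition particle receptor, at 22.8, 21.4 and 14.8 against 44.5, 27.5 and 40.8 FPKM. SEC61A1 was at 19.6, 17.6 and 13.5 FPKM against 25.3, 28.02 and 32.9. Over 29 translocation and glycosylation genes, none of them in the unfolded protein response list, 21 lay above 0, with a median log2 fold change of 0.20 and a camera p of 0.0413. Over 22 vesicle transport genes 18 lay above 0, with a median of 0.20 and a camera p of 0.0364. Both are consistent with a wider rise, as a hypothesis, yet with an estimated correlation p was 0.232 and 0.0828, and with fry in one direction 0.0609 and 0.0058.

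Control 1 may carry altered copies of whole chromosomes. With the genes of a chromosome parted at the median position into 2 parts, both parts of chromosome 27 lay below the range of the other 5 libraries, at -0.575 and -0.59, and so did both parts of chromosome 15, at -0.493 and -0.511. Both parts lay above that range on chromosome 14, at 0.31 and 0.396, and on chromosome 28, at 0.279 and 0.366. A change of copy number in part of the cells is a candidate explanation, and DNA was not measured. In control 2 chromosome 15 lay 0.20 above, which control 1 raises in part, since it is among the 5 libraries compared.

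Among the 10 splits of the libraries, 6 called at least 1 list by camera, and the highest of the other splits called 5 lists against 1 for the real split. With fry in either direction the real split called 4 lists and the highest of the other splits 0, so 1 of the 10 splits reached that number. The split that set controls 1 and 2 with MAT2A-inhibited morula 1 against the rest called these 5 lists by camera. The unfolded protein response list was among them, and it was the 1 list called in each of the splits that set controls 1 and 3, or controls 2 and 3, with that morula. The 10 splits are too few for a share under 0.05.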
